A study of Homo sapiens with 6 samples.

How the data were processed

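The series measured gene expression by RNA sequencing in 6 libraries, 2 each of wild-type U2OS cells and of 2 clones with heterozygous TERT mutations. Total RNA was extracted with TRIzol and libraries were made with a stranded total RNA kit, per the labels' protocols. The analysis used 1 deposited table of 60612 genes with FPKM values (fragments per kilobase of transcript, relative to the library total) rounded to 2 decimals, which the authors made at gene level with RSEM according to the table's name. The submitters' processing notes name Trim Galore 0.6.4, Trimmomatic 0.39, cutadapt 2.10, STAR 2.7.9a, featureCounts 2.0.1 and DESeq2 1.20.0, and the build GRCh38, with no role or order. RSEM is not among them, and its version, the annotation release, the strand setting and the filters are not given in the sources used here. Gene types and positions are those of the deposited table. Of 58300 genes shared with GENCODE 29 (GRCh38), 74.7% had identical coordinates, and 99.7% of the gene identifiers were found in the gene name table used to match symbols.

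Columns were matched to samples by name. The columns named U2OS with a number carry the source name of the wild-type samples and their replicate numbers. The other 4 columns of per-sample values carry 2 further names that the labels do not link to either clone, so they were not used in any step, and the clone libraries were not analysed here. The comparisons planned before the data were examined were therefore not made under this matching rule. They covered each clone, and the mean of both clones, against the wild type, and the clones against each other. The overlap of both clones, gene list tests and chromosome shifts were planned too. No p-value is reported for a difference between groups.

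FPKM is relative within a library, so an abundant RNA lowers all other values, and it hides the number of fragments behind a value. Each library was multiplied by a median-of-ratios factor (1.006 for replicate 1 and 0.994 for replicate 2), computed over genes above 0 in both. A gene was called expressed at 1 FPKM or more in both libraries. Means and sample SDs are over the 2 libraries, and with 2 values they are imprecise. Gene lists (25) were fixed before the data were examined, and 1 list of cell cycle and tumour suppressor genes was added afterwards, before its values were seen. Of 614 list members 601 were measured. The list of mitochondrially encoded genes is not analysed here. The planned rule for named genes used test results. It was replaced, before the list values were seen, by TERT, the 3 highest and the 2 lowest members of each list. Some genes that this rule names are not reported here. Genes named beyond that rule (other genes listed at 0, SLC6A3, RB1, the type I collagen pair, IL6, PTPRC, the most abundant RNAs, entries sharing a place, and the passing blood and epithelial markers) were chosen after their values were seen. An entry listed at 0 can be a failed estimate, as other entries at the same place take its reads.

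Depth was estimated from the low values. Where whole fragments are counted, FPKM times effective length moves in steps of 1 fragment. The step was fitted by its periodicity over genes with 1 listed transcript of 800 to 4000 bases, with transcript lengths from GENCODE 29. It gave 43900000 fragments from 704 genes in replicate 1 and 27500000 from 595 genes in replicate 2. At an effective length of 2000 bases, 1 FPKM then stands for 88 and 55 fragments, a counting error of 10.7% and 13.5%. The same 5378 candidate genes were offered to the fit in 3 simulated libraries. Of these genes, 750 to 792 entered it by the same limits, more than the 704 and 595 of the real libraries. In the simulated libraries the estimate missed the true depth by at most 4.8%, and the error in the real libraries can be larger. These errors cover counting only, since copies made by PCR are not independent molecules. Alternatives were FPKM as deposited, quantile normalization, a threshold of 0.1 FPKM and each library alone. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.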

Results

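RNA was measured in U2OS cells, a human osteosarcoma line that maintains its telomeres without telomerase (alternative lengthening of telomeres, ALT). The series holds 6 libraries in 3 groups of 2, namely wild-type cells and 2 clones made with CRISPR-Cas9 that carry heterozygous mutations of TERT, the gene of the catalytic subunit of telomerase. The series was set up to compare the clones with the wild type. Only the 2 wild-type libraries are reported here, because 4 value columns of the table bear names that the sample labels do not tie to either clone, and those columns were not used. No comparison between genotypes was therefore made, and the values below describe the wild-type state. All levels are FPKM after a scale factor per library, as mean ± SD over the 2 libraries (n = 2). Nothing in the labels says that the libraries came from separate cultures, so the SD measures only the spread between these 2 samples. The steps between low values gave estimated depths of 43900000 fragments in replicate 1 and 27500000 in replicate 2.

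TERT itself was near the limit of expression in wild-type cells. The gene (ENSG00000164362, chromosome 5, 1253147 to 1295068, minus strand, GRCh38, protein-coding) stood at 0.31 FPKM in replicate 1 and 1.36 FPKM in replicate 2, a mean of 0.84 ± 0.74. The library values differed 4.37-fold, so no level of TERT narrower than this range was resolved. TERC, the RNA template of telomerase, was listed at 0 in both libraries. Its place on chromosome 3 carries a second entry on the same strand, named Telomerase-vert (169764610 to 169765047, GRCh38), and that entry stood at 8.92 ± 0.72 FPKM. Of the 18 measured members of the telomerase and shelterin list, 16 were at 1 FPKM or more in both libraries. DKC1, the pseudouridine synthase that binds telomerase RNA, was the highest at 69.1 ± 1.76. NHP2 of the same complex reached 49.1 ± 0.15, and the shelterin subunit TERF2 reached 31.7 ± 3.14. These 3 means were each far above the TERT level in both libraries.

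Genes next to TERT in 5p15.33 were mostly expressed at higher levels than TERT. Between the tip of the short arm and 1 Mb (1000000 bases) beyond the gene, the table lists 26 other protein-coding genes. Of these, 18 were at 1 FPKM or more in both libraries, and the same 18 exceeded the higher of the TERT values in both libraries. Among all protein-coding genes listed, 59.5% were at 1 FPKM or more in both libraries. Whether the region differs from other regions was not tested. CLPTM1L, the next protein-coding gene towards the centromere (chromosome 5, 1317752 to 1345099), was the most abundant at 359 ± 2.15 FPKM. SDHA, a subunit of succinate dehydrogenase, stood at 132 ± 0.75, and TRIP13, a mitotic checkpoint ATPase, at 64.6 ± 6.45. SLC6A19 and SLC6A18, the transporter genes on the other side of TERT, were listed at 0 in both libraries, and SLC6A3 had a mean of 0.01 ± 0.01. The preset list of TERT neighbours, which overlaps this region, had 18 of 23 measured members at 1 FPKM or more in both libraries and a median of 7.52.

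**Figure D1:**
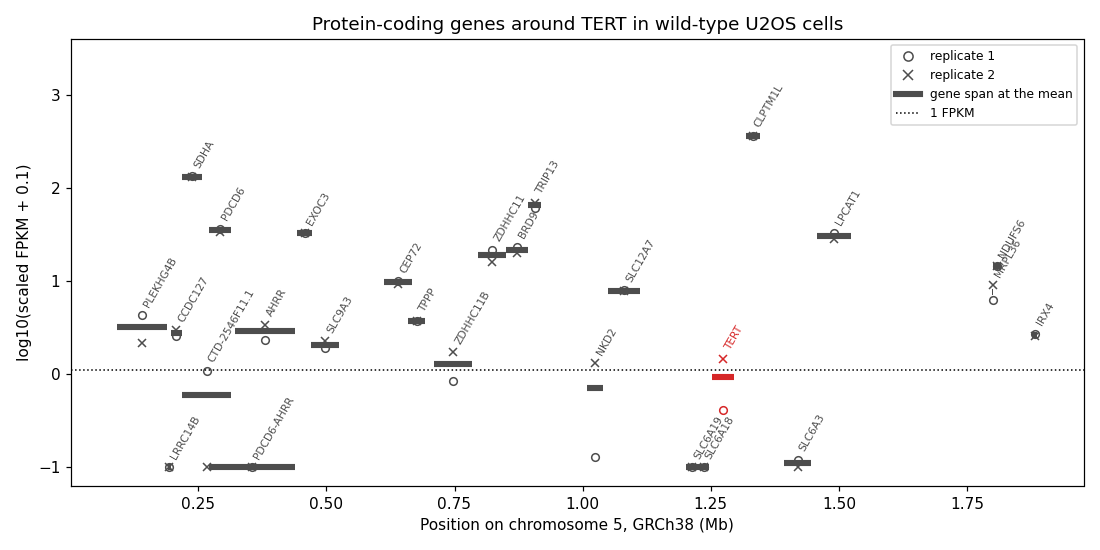
Scaled FPKM (vertical axis, log10 of the value plus 0.1) of protein-coding genes by position on chromosome 5 in Mb (GRCh38). Bars span each gene at its mean of 2 wild-type libraries, open circles are replicate 1, crosses are replicate 2, and the dotted line is 1 FPKM. TERT, in red, lies at a mean of 0.84, below CLPTM1L at 359, and SLC6A19 and SLC6A18 on its other side are listed at 0.

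Genes of the ALT and telomere recombination list were expressed throughout. Membership in the list does not say whether a gene promotes or restrains ALT. All 28 measured members of the ALT and telomere recombination list were at 1 FPKM or more in both libraries, with a list median of 22.2. The highest were the histone H3.3 chaperone DAXX at 87.0 ± 11.1, RAD51AP1, which promotes strand invasion in recombination, at 78.2 ± 7.49, and ATRX, the chromatin remodeller that works with DAXX, at 70.4 ± 3.66. The lowest were ASF1B at 8.57 ± 0.85 and PML at 7.27 ± 0.82. For ATRX as for the other genes, a gene-level FPKM does not show whether the transcript is intact or translated. All 26 R-loop processing genes were likewise at 1 FPKM or more, with a list median of 69.0. The splicing factor SRSF1 reached 411 ± 23.8 and the RNA helicases DDX5 and DHX9 reached 410 ± 24.5 and 203 ± 6.46. RNASEH1, the nuclease that degrades RNA in RNA-DNA hybrids, was the lowest of this list at 12.2 ± 3.23, after TOP3B at 14.95 ± 0.76.

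Cell division genes were among the most abundant groups. All 36 kinetochore, spindle and mitotic entry genes were at 1 FPKM or more in both libraries, with a median of 80.3. The mitotic kinase CDK1 stood at 314 ± 1.28, securin (PTTG1) at 290 ± 6.95 and the kinetochore protein CENPF at 274 ± 22.6, whereas TTK and SGO1 were lowest at 26.9 ± 0.87 and 25.8 ± 0.21. All 31 DNA replication and S phase genes were also at 1 FPKM or more, with a median of 52.0, led by the helicase subunit MCM4 at 659 ± 1.38, RRM2 at 535 ± 10.4 and TYMS at 488 ± 26.9. GINS3 at 10.9 ± 1.69 and CHAF1B at 6.93 ± 1.097 were the lowest of them. Among replication-dependent histone genes, 31 of 44 were at 1 FPKM or more in both libraries, 12 were below it in both and 7 were listed at 0. H2BC4 reached 928 ± 71.9, H1-2 729 ± 44.9 and H2BC5 646 ± 40.2. Many histone genes are similar in sequence, so the split of reads between such members can be uncertain. In the ribosome biogenesis and MYC list all 23 genes were at 1 FPKM or more (median 60.6), from NPM1 at 3284 ± 66.4, NCL at 413 ± 23.7 and WDR43 at 140.1 ± 0.17 down to NOP16 at 11.3 ± 0.55 and PPAN at 2.67 ± 0.44.

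The p53 target list had 29 of 31 members at 1 FPKM or more in both libraries, with a median of 12.4. PLK2 was highest at 246 ± 8.31, then CCNG1 at 92.4 ± 9.64 and the ubiquitin ligase MDM2 at 90.1 ± 5.50. GDF15 and SPATA18 were the exceptions below 1 FPKM in both libraries, at 0.35 ± 0.37 and 0.045 ± 0.063. Of the FOXO factors and targets 16 of 18 were at 1 FPKM or more (median 5.94). CITED2 led at 50.4 ± 0.81, followed by SESN3 at 41.8 ± 3.40 and RICTOR at 23.8 ± 0.74, while KLF2 was at 0.80 ± 0.22 and IRS2 was listed at 0. Among Wnt target genes 11 of 17 were at 1 FPKM or more (median 4.12), with CCND1 (cyclin D1) at 142.6 ± 1.74, TCF7L2 at 56.5 ± 4.02 and MYC at 36.2 ± 0.99. SP5 and APCDD1 were listed at 0.

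The shares of innate immune genes at 1 FPKM or more in both libraries lay on either side of that of all protein-coding genes (59.5%). They were 65.8% for interferon-stimulated genes and 50.0% for the NF-kB and inflammatory cytokine list. Among interferon-stimulated genes 25 of 38 were at 1 FPKM or more in both libraries, with a list median of 3.29. PARP14 stood at 46.1 ± 1.17 and SP110 at 30.5 ± 3.92. XAF1 and EPSTI1 were listed at 0. In the NF-kB and inflammatory cytokine list 12 of 24 genes were at 1 FPKM or more, 12 were below it in both libraries, and the median was 0.81. NFKB2, NFKBIA and the cytokine LIF reached 32.7 ± 8.53, 23.9 ± 1.29 and 21.96 ± 0.72. IL6 stood at 1.16 ± 0.17, and CXCL1, CXCL2, IL1B, CXCL10, CCL5 and MMP1 were listed at 0.

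Matrix genes were abundant whereas most markers of mature bone cells were not. Of 36 extracellular matrix genes 30 were at 1 FPKM or more in both libraries (median 30.3). SPARC, a collagen-binding glycoprotein, stood at 631 ± 14.5, the laminin chain LAMC1 at 301.2 ± 2.48 and CCN1 at 222 ± 0.80. The type I collagen chains differed, with COL1A1 at 186 ± 8.28 and COL1A2 at 0.14 ± 0.03, a gap larger than the spread of either gene. THBS2 and DCN were listed at 0. In the osteoblast lineage list 8 of 22 genes were at 1 FPKM or more, 13 were below it in both libraries and the median was 0.18 (0.21 in replicate 1 alone and 0.11 in replicate 2 alone). BMP4 at 54.4 ± 2.23 and the osteoblast transcription factor RUNX2 at 14.6 ± 3.03 were highest. SP7, IBSP, DLX5 and MEPE were among 7 genes listed at 0.

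Metabolic and stress lists were expressed almost throughout. The unfolded protein and integrated stress response list had 23 of 25 genes at 1 FPKM or more (median 14.9), led by the endoplasmic reticulum chaperones HSP90B1 at 470 ± 16.9 and HSPA5 at 182 ± 6.42 and by ATF4 at 170 ± 2.57, with CHAC1 at 1.00 ± 0.26 and STC2 at 0.21 ± 0.20. Of the cholesterol synthesis genes 23 of 24 passed 1 FPKM (median 23.9), with FDFT1 at 85.3 ± 6.06, HMGCS1 at 78.7 ± 9.42 and TM7SF2 at 2.15 ± 0.77. The hypoxia and glycolysis list had 21 of 23 at 1 FPKM or more (median 36.5). ENO1, LDHA and ALDOA, enzymes of glycolysis, stood at 1229 ± 103, 984 ± 75.0 and 427 ± 7.99, whereas CA9 was at 0.20 ± 0.03 and ANGPTL4 was listed at 0.

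HOX genes, which record position along the body axis, were expressed in 27 of 38 cases (1 FPKM or more in both libraries, median 2.94). HOXB7 at 82.1 ± 2.703, HOXA7 at 49.4 ± 7.69 and HOXC6 at 30.8 ± 2.21 were highest. HOXD12 was at 0.015 ± 0.021 and HOXD13 was listed at 0.

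Markers of blood and epithelial cells were mostly low, whereas neural markers and muscle and fat markers were mixed. Among blood cell markers 2 of 13 were at 1 FPKM or more in both libraries, CD68 at 2.66 ± 0.32 and CORO1A at 2.08 ± 0.19, and 7 were listed at 0, which put the list median at 0. PTPRC, the leukocyte marker CD45, was at 0.92 ± 0.74. Among epithelial markers 3 of 13 passed, namely KRT7 at 6.11 ± 0.42, EPCAM at 4.83 ± 0.82 and CLDN4 at 1.29 ± 0.05. The median of the epithelial list was 0.27, with 0.07 in replicate 1 alone and 0.47 in replicate 2 alone. KRT5, ESRP1, GRHL2 and OVOL1 were listed at 0. Neural markers passed in 7 of 12 cases (median 1.74), led by TUBB3 at 65.6 ± 1.11, NES at 27.5 ± 0.31 and SNAP25 at 8.19 ± 1.80, with DCX and STMN2 listed at 0. Of muscle and fat markers 5 of 12 passed (median 0.68), led by the troponin gene TNNT1 at 103 ± 0.18, PPARG at 26.1 ± 3.62 and TNNT2 at 12.5 ± 2.58, with MYOD1, MYOG, FABP4 and ADIPOQ listed at 0.

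**Figure D2:**
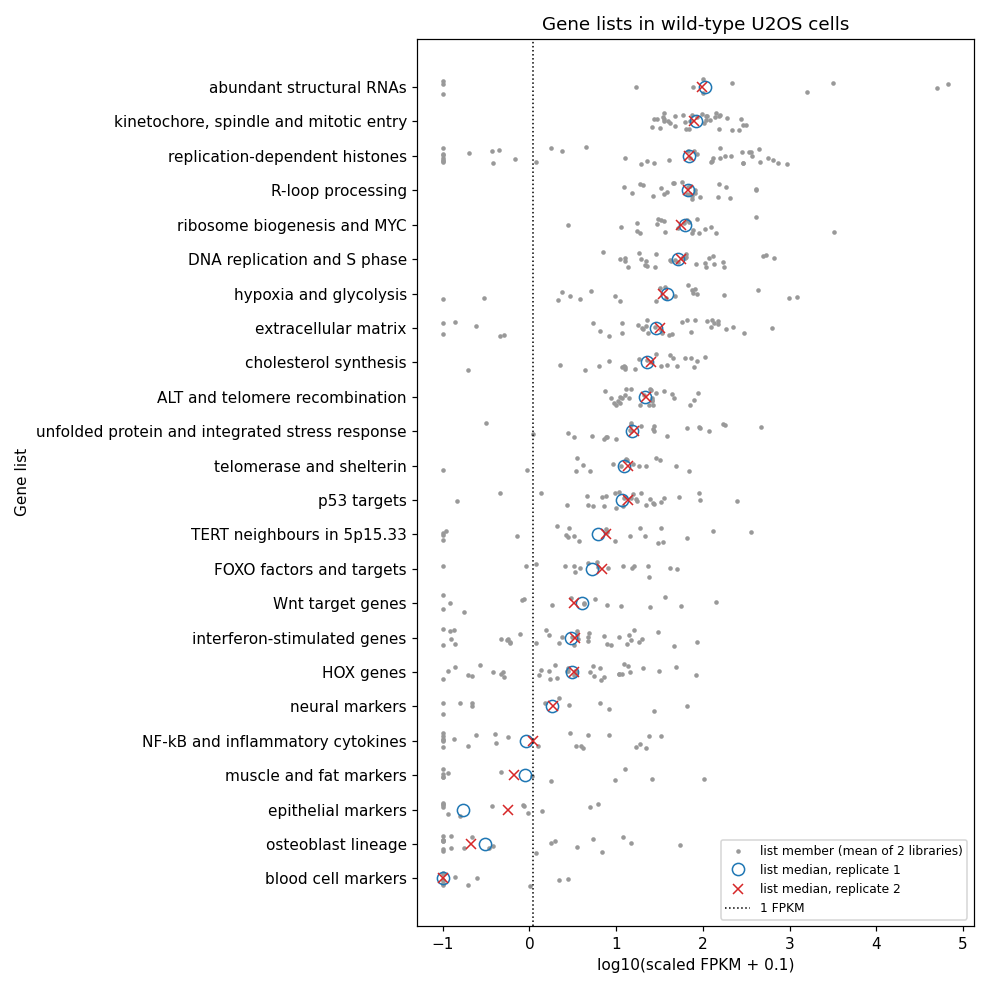
Levels of 24 preset gene lists in wild-type U2OS cells, as log10 of scaled FPKM plus 0.1 (horizontal axis), ordered by list median. Grey points are list members (mean of 2 libraries), open circles and crosses are the list medians in replicates 1 and 2, and the dotted line is 1 FPKM. Mitotic genes (median 80.3) and R-loop processing genes (69.0) lie well to the right of osteoblast lineage genes (0.18) and blood cell markers (0).

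Across the transcriptome, 14502 genes were at 1 FPKM or more in both libraries. They included 11861 protein-coding genes, 59.5% of those listed, and 1402 lncRNA genes, 8.3% of those listed. Another 2066 genes reached 1 FPKM in 1 library only. Over the 14502 genes the libraries correlated at r = 0.981 (Pearson, log2 values) and rho = 0.979 (Spearman). These are correlations across genes within a pair of libraries, and genes are not independent replicates. The values of 96.7% of these genes lay within 2-fold of each other. The median difference narrowed with level, from 1.26-fold for 2420 genes with means of 1 to 3 FPKM to 1.06-fold for 1098 genes above 100 FPKM. The requirement of 1 FPKM in both libraries bars large differences at low means, so the agreement there is partly set by the filter.

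Short structural RNAs took a large share of summed FPKM. FPKM divides by transcript length, so a short RNA weighs more in that sum than in sequenced fragments. Genes annotated as misc_RNA, the class of 7SK and signal recognition particle RNA, held 23.7% ± 2.32 of summed FPKM and protein-coding genes held 67.7% ± 2.45 (n = 2). 7SK, which regulates transcription elongation, stood at 89860 ± 12490 FPKM, and RN7SL2 and RN7SL1, which encode signal recognition particle RNA, at 67520 ± 11470 and 50200 ± 7349. RPPH1, the RNA of ribonuclease P, was at 3130 ± 425, and a second RPPH1 entry at the same place was at 1438 ± 103, so the split of reads between them is uncertain. Of the 12 RNAs in the abundant structural RNA list, 9 were at 1 FPKM or more in both libraries (median 101), and RN7SK, RMRP and VTRNA1-1 were listed at 0. RMRP and RN7SK have second entries at their places, at 1746 ± 392 FPKM for RMRP and at the 7SK value above. The most abundant protein-coding entries after MTRNR2L12 were ACTB (beta-actin) at 9164 ± 379, RPL4 at 4477 ± 104 and RPS21 at 3622 ± 153. MTRNR2L12, at 72740 ± 1505, is a nuclear copy of mitochondrial ribosomal RNA, so its reads are uncertain. It is counted in the protein-coding share above. No gene on the mitochondrial chromosome was listed, so mitochondrial reads had no entry of their own. The origin of the MTRNR2L12 reads was not tested.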

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

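Apart from the use of deposited FPKM for TERT, these alternatives were chosen after seeing the data. No paired analysis was possible because only the wild-type columns were matched to samples by name and the other columns were left out by that rule, so no groups were compared, and for the same reason none of the planned tests between groups was run. The count of 14502 genes at 1 FPKM or more in both libraries was 14510 with FPKM as deposited and 14509 with quantile normalization. A threshold of 0.1 FPKM raised it to 19845, by its construction, and at that level a 2000-base transcript holds under 10 fragments in both libraries. With each library alone the count lay between 15492 and 15578. The TERT mean of 0.84 FPKM was 0.84 as deposited and lay at 0.31 or 1.36 with a single library, so either library decides which side of 1 FPKM it takes. For the 20 lists with a median of 1 FPKM or more, the median in a single library was 0.77 to 1.13 times the value reported. For lists with lower medians, the values in replicates 1 and 2 alone were 0.07 and 0.47 for epithelial markers (reported 0.27), 0.21 and 0.11 for osteoblast lineage (0.18), 0.79 and 0.56 for muscle and fat markers (0.68) and 0.82 and 0.99 for NF-kB and inflammatory cytokines (0.81), while the blood cell median was 0 in both.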

Other observations

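Cell cycle regulators were described by a list added after the column names were seen. Of its 14 genes 12 were at 1 FPKM or more in both wild-type libraries. CCND1 was highest at 142.6 ± 1.74 FPKM, followed by its partner kinase CDK4 at 111.0 ± 9.75 and MDM2 at 90.1 ± 5.50. RB1 stood at 20.1 ± 0.14. The exceptions were CDKN2A and CDKN2B, inhibitors of CDK4, at 0.195 ± 0.009 and 0.005 ± 0.007. Expression by chromosome, taken over the autosomes and X only, was also uneven. The share of protein-coding genes at 1 FPKM or more in both libraries ran from 51.1% on chromosome X and 51.9% on chromosome 11 to 65.9% on chromosome 14, whose expressed genes also had the highest median at 21.4 FPKM. Chromosome 19 had the lowest median at 8.94 FPKM.

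Of the tests below, that of the spread at the TERT level was fixed before its result was seen, and the others were chosen afterwards. TERT differed 4.37-fold between the wild-type libraries. Against 1666 protein-coding genes with means within 2-fold of TERT, its log2 difference of 2.13 lay at percentile 92.0, with a median of 0.57 and a 95th percentile of 2.53. That percentile was below the 95th, the limit fixed for an ordinary spread between these libraries at that level. The 1666 genes were matched to TERT by FPKM only, not by transcript length or fragments. Genes lacking FPKM in 1 library or both were left out. Part of the spread among the 1666 genes can be counting error that TERT need not share. The percentile therefore cannot decide whether the TERT difference is ordinary. Whether counting error alone could account for the 4.37-fold difference depends on the transcript assumed. With the longest listed transcript (4018 bases, 52 and 144 fragments) the lower 95% bound of the fragment ratio was 3.20. With the shortest (406 bases, 3 and 8 fragments) it was 1.02. The 4.8% error of the depth estimate in simulated libraries covers that bound, and the error in the real libraries can be larger. Fragments per transcript are not given, so counting error stays open. No biological explanation was tested, since both libraries belong to 1 group.

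The zero listed for TERC may be a product of the annotation. The second entry at its place on the same strand, Telomerase-vert, had 8.92 FPKM and was at 1 FPKM or more in both libraries, so reads of the locus counted under a second entry at the same place would account for it. The table holds 282 same-strand pairs of entries that overlap by at least 80% of each. In 134 of them at least 1 entry was at 1 FPKM or more in both libraries, and in 31 of these the other was listed at 0. Zeros were common in general, since 25075 of all 60612 entries were above 0 in replicate 1 and 24101 in replicate 2. The 31 pairs are therefore no evidence for the annotation account of TERC. Whether Telomerase-vert reads come from mature TERC was not tested, and the table gives no read positions to test it.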
